A study of Mus musculus with 6 samples.

How the data were processed

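The series holds RNA sequencing of primary mouse podocytes, the epithelial cells that wrap the capillaries of the kidney glomerulus. The labels describe 6 samples without treatment in 2 groups, 3 labelled as wild type and 3 labelled as a knockout of SIRPa. Per the labels' protocols, glomeruli were isolated with magnetic beads and plated for culture, polyadenylated RNA was selected, and strand-marked paired-end libraries were made by the dUTP method. No label says whether the 3 samples of a group came from separate animals.

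The authors deposited 1 table of genes for the whole series. Per the file headers, it pairs each gene identifier with a symbol, a chromosome, a start, an end, a strand, transcript identifiers and functional terms, followed by 6 FPKM columns and 6 count columns. The submitters' processing notes list cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6, as well as DESeq2 and edgeR without versions, and the genome build mm9, with no role or order. The gene annotation release and the rule that decided which genes have a row are not given in the sources used here.

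The 12 columns of expression values were not analysed. Their headings carry the letters A and B with the numbers 1 to 3, whereas the samples are titled WT and KO with the numbers 1 to 3. No label or header used here ties a letter to a genotype. Column order does not name a genotype, and assigning the letters by the expression of the targeted gene would have assumed the outcome for that gene. The columns, with the rows of Sirpa, Pkm, Cd47 and a few other genes, were viewed when the units of the table were examined. The Sirpa row seen in that view was not used to assign the letters. A contrast of the letters with its sign left open was not made either, since columns that match no sample were kept out of every computation. No count, FPKM value, library depth, fold change or test derived from them is reported. The comparison of knockout with wild type, the named-gene rule beyond Sirpa, Pkm and Cd47, the tests of gene lists and the enrichment of functional terms, all fixed before the data were examined, were therefore not run.

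What was computed rests on the annotation columns alone. Gene positions, 1-based as in the table, were compared by Ensembl identifier with GENCODE M21, an annotation of the mouse build GRCm38. A gene counted as placed alike when chromosome, start and end were all equal, after adding the prefix chr to the names X and Y and writing MT as chrM. The 95% intervals of shares are Wilson intervals. Genes were called overlapping when their spans shared at least 1 bp. Exon structures and gene types were taken from GENCODE M21. Symbols of 38 gene lists, fixed before the data were examined, were looked up in the table by exact match, and then through the older and alternative symbols of the reference tables. As a check of the code, the positions of 200 of the table's 31321 genes were shifted and compared with the table's own positions, and 200 were found. This does not test the match with GENCODE M21. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used.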

Results

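The study set podocytes labelled as a SIRPa knockout against podocytes labelled as wild type, to examine which pathways follow a reduction of this receptor, and its title names podocyte metabolism, inflammation and the pyruvate kinase isoform PKM2. The labels give 3 samples to each genotype. The gene table covered 31321 genes, but its columns of values are headed by letters that the labels do not tie to a genotype. No expression level is therefore given for either group, and no difference between knockout and wild type is reported. The account below is limited to the genes the study concerns, where they lie and how the table represents them.

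Sirpa (ENSMUSG00000037902), the targeted gene, encodes an inhibitory membrane receptor that binds CD47 and recruits the tyrosine phosphatases SHP-1 and SHP-2. The table placed it on chromosome 2 from 129592835 to 129632228, on the + strand, a span of 39394 bp that equals the GRCm38 position in GENCODE M21. The table listed 11 Sirpa transcripts, all of them among the 14 of GENCODE M21, where 9 of the 14 are protein-coding. The coding transcript Sirpa-203 has 8 exons with 1527 coding bases, and Sirpa-211 has 9 exons with 1539 coding bases. Exon number does not set this length, as Sirpa-201 has 8 exons with 1539 coding bases and Sirpa-204 has 9 with 1527. Other coding transcripts are shorter, such as Sirpa-208 with 474 coding bases. The labels do not say which part of the gene was deleted, and the table holds 1 row for the whole gene. No other gene of the table overlapped Sirpa. The nearest protein-coding genes with a row were F830045P16Rik, which ends 56232 bp before it, and Stk35, a serine/threonine kinase gene that starts 168288 bp after it. Within 5 Mb on either side, 123 protein-coding genes had a row.

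Related receptors had rows of their own. Sirpb1a, Sirpb1b and Sirpb1c, members of the same receptor family, lie on the - strand of chromosome 3. Sirpb1a spans 15371653 to 15426520, Sirpb1b spans 15495751 to 15575065 and Sirpb1c spans 15795145 to 15848528. Cd47 (ENSMUSG00000055447), which encodes the ligand of SIRPa, was placed on chromosome 16 from 49800533 to 49911091. GENCODE M21 ends this gene at 49915010, beyond the end given in the table. The table still listed a Cd47 transcript that ends at 49915010 in GENCODE M21. The reason for the earlier end was not tested. Ptpn6 and Ptpn11, which encode SHP-1 and SHP-2, were among the 17 of 17 symbols of the SIRPa and CD47 list that had a row.

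Pkm (ENSMUSG00000032294), the gene for muscle-type pyruvate kinase, which makes pyruvate in the last step of glycolysis, was placed on chromosome 9 from 59656368 to 59679375, on the + strand. PKM1 and PKM2 are splice forms of this gene that use alternative exons. In GENCODE M21 the transcripts Pkm-202 and Pkm-201 each have 11 exons and share 8 internal exons. Apart from the outer ends, they differ in exon 9 of the transcript, which runs from 59675029 to 59675195 in Pkm-202 and from 59675568 to 59675734 in Pkm-201. Each of these exons is 167 bp long. The exon nearer to the start of the gene is the one known from PKM1, and the other is the one known from PKM2. The table gave 1 row to Pkm, with 11 transcript identifiers on it, so PKM1 and PKM2 transcripts share its values. The predicted gene Gm49759 overlapped Pkm on the same strand.

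**Figure D1:**
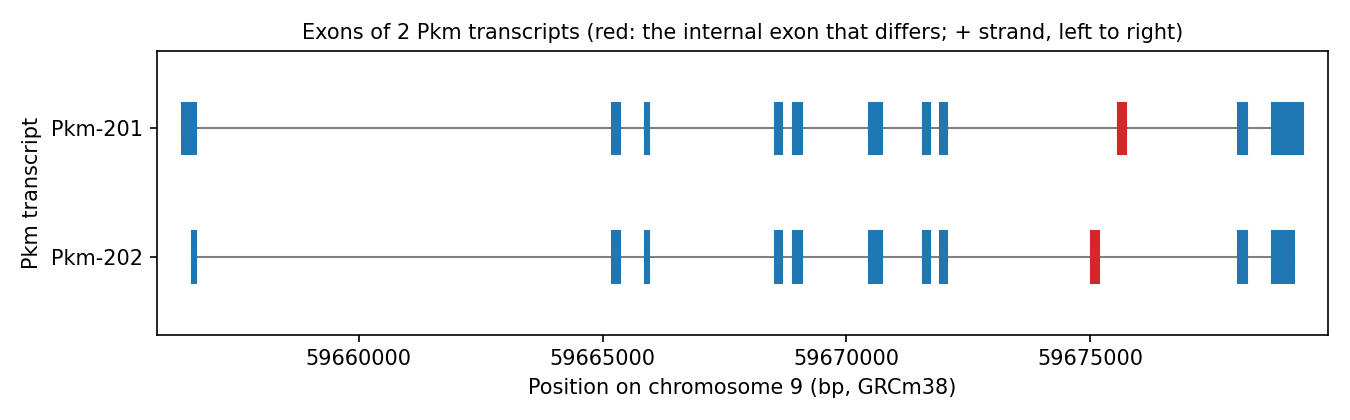
Exons (boxes) of the transcripts Pkm-202 and Pkm-201 along chromosome 9, in bp of GRCm38, from GENCODE M21, with the internal exon that differs in red. The red exon of Pkm-202 starts at 59675029 and that of Pkm-201 at 59675568, and both belong to the 1 row that the table gave to Pkm.

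Of the 38 gene lists fixed in advance, 29 had a row for every symbol. All 38 podocyte symbols fixed in advance had a row, among them Nphs1, which encodes the slit diaphragm protein nephrin, and the transcription factor Wt1. So did 25 of 25 glycolysis symbols, such as Hk2 and Ldha, 34 of 34 symbols of the TCA cycle and pyruvate dehydrogenase, 36 of 36 of NF-kB and inflammatory cytokines, such as Il6 and Ccl2, and 15 of 15 of the inflammasome. Aldoa, a glycolytic aldolase, stood on more than 1 row. For oxidative phosphorylation 75 of 90 symbols had a row, in a list that held older and newer names of the ATP synthase subunits. Every symbol without a row there was such a name, and its other name had a row, so no gene of that list was missing. The extracellular matrix list had 40 of 42, without Cyr61 and Ctgf, whose other names Ccn1 and Ccn2 had rows. The list of nuclear PKM2 and HIF-1 targets had 21 of 22, without Ca9. Among markers of other cells, 32 of 32 macrophage and monocyte symbols, 18 of 18 endothelial, 15 of 15 mesangial and pericyte, and 14 of 14 fibroblast symbols had a row. The proximal tubule list had 16 of 18, and the distal nephron and collecting duct list 15 of 18. The lymphocyte and natural killer list had 14 of 22, the neutrophil list 8 of 13, the dendritic cell list 9 of 13 and the erythrocyte list 7 of 8. Over all protein-coding genes of GENCODE M21, 80.8% had a row. Lists of other cell types were complete too, so the complete podocyte list does not set podocyte genes apart. A row shows that the gene was listed and gives no level of expression.

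The table's own functional terms tied 37 genes to the GO term glycolytic process, Pkm included, and 304 to inflammatory response. Only genes carrying the term itself were counted. Genes with related terms alone, such as Sirpa for inflammatory response, were left out. The KEGG pathway of glycolysis and gluconeogenesis held 62 genes, that of HIF-1 signalling 98 and that of NF-kappa B signalling 88. Sirpa carried 53 GO terms, among them the engulfment step of phagocytosis, both negative and positive regulation of phagocytosis, cytoskeleton organization and cell migration. Sirpa also carried negative regulation of inflammatory response and negative regulation of I-kappaB phosphorylation. It was not assigned to any of these 3 KEGG pathways. Of the 31321 genes, 17664 had GO terms, 6767 had KEGG pathways and 8318 had Reactome pathways.

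By gene type, 17793 of the 22028 protein-coding genes of GENCODE M21 had a row (80.8%), against 1932 of 5854 lincRNA genes (33.0%) and 3951 of 9941 processed pseudogenes (39.7%). Shares of other noncoding types were higher, with 1939 of 2959 antisense genes (65.5%) and 577 of 790 processed transcripts (73.0%), or lower, with 392 of 2642 unprocessed pseudogenes (14.8%). Of the listed genes, 15521 (49.6%) overlapped another listed gene on either strand, and 6823 (21.8%) overlapped one on the same strand. Pkm overlapped a gene on its own strand and Sirpa overlapped none.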

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

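The alternatives given here were chosen after seeing the data, since those fixed before the data were examined all concern expression values and were not run: the pseudocount, the filters on low FPKM, the scalings, the moderation settings, the weights, the leaving out of single libraries, the minimum fold, the count models, the other set tests and the other term sizes. No paired analysis was possible between the genotypes because no column could be assigned to one. The headings do form 2 sets of 3 with shared numbers, and a paired contrast of the letters, of unknown sign, was left out by choice, as were all computations on columns that match no sample. The share of genes placed as in GRCm38 was 90.9% with exact equality. It was 94.9% when start and end could each differ by 100 bp, 97.0% with 1000 bp, 99.994% when an overlap on the same chromosome sufficed, and 85.6% among protein-coding genes alone. Symbols of the fixed lists with a row numbered 883 of 924 by exact match and 884 after the lookup of other symbols. That lookup missed Cyr61, Ctgf and most of the ATP synthase names, whose genes had rows. Genes overlapping another listed gene fell from 15521 on either strand to 6823 when the same strand was required, which is narrower by construction. Sequencing depth was not examined. The rule that decided which genes have a row is unknown, so whether depth limits the counts of rows, list members and overlaps is open.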

Other observations

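The genome build named in the submitters' processing notes is mm9, and the positions in the table were compared with GRCm38, which is also called mm10. Of the 31231 identifiers shared with GENCODE M21, 28385 had the same chromosome, start and end there, a share of 90.9% (Wilson 95% interval 90.6% to 91.2%), and 31229 overlapped the same gene. All shared identifiers were compared and none were sampled, so the interval does not measure how far the share moves with the setting. The comparison was added after a first look at the table, in which positions resembled GRCm38. Before the share was computed, at least 90% had been set as a share that positions on mm9 would not give, and under 10% as one that they would. Protein-coding genes alone gave 85.6%, under the first bound and far above the second. These values argue against mm9 for the gene positions in this table. Sirpa and Pkm matched GRCm38 exactly, and Cd47 matched in its start but not in its end. Alignments were not examined, so the build the reads were aligned to was not tested. A further 90 identifiers had no counterpart in GENCODE M21, and 2846 shared genes differed in a start, an end or the chromosome. A candidate explanation for these, which was not tested, is a later annotation of the same build.

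Chromosome names in the table were of mixed form. The 19 autosomes carried the prefix chr and held 30119 genes, whereas X with 1090 genes, Y with 75 and MT with 37 did not. Symbols were not unique either: 60 symbols stood on more than 1 row, 124 rows in all, among them that of the glycolytic gene Aldoa.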
